A study of Homo sapiens with 3 samples.

How the data were processed

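RNA of K562 cells, an established line from a chronic myelogenous leukaemia, was sequenced from 3 libraries. The cells had been infected with retrovirus made in packaging cells of the HEK293 type and carrying an empty vector, EVI1-WT or EVI1+18, both EVI1 forms with an HA tag of 3 copies. Per the labels' protocols, cells positive for the GFP marker were sorted 3 days after infection and then grown for sampling, RNA was taken with an RNeasy column kit, and libraries were made with a TruSeq RNA kit of version 2. Each construct has 1 library, so no spread between replicates could be measured, no test was run and no p-value is given.

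Per the file headers, the authors deposited 1 gene table per library with an expected count, a TPM value and an FPKM value for each of 26334 genes, named by symbol over RefSeq transcripts. The deposited expected count is an estimate in which a read that fits several transcripts is shared between them, and 3.09%, 3.02% and 3.06% of values (empty vector, EVI1-WT and EVI1+18) lay more than 0.001 from a whole number. The TPM values, which the authors scaled by effective length to the same total in every library, served as an alternative. The FPKM values the authors deposited were not used in any comparison. Other columns of the deposited tables, per the file headers, hold transcript length and effective length, and the first was used only for a check of length. The genome build was hg19 and reads were converted with bcl2fastq, per the submitters' processing notes. The aligner, the counting tool, the annotation release and any use of strand are not given in the sources used here. Reads of near-identical copies, of read-through transcripts and of overlapping or antisense genes are therefore uncertain, and the genes recognised as such are named as uncertain where their values are printed. The reference genome at hand was of another build, so no coordinates are printed; it served for GC content only.

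Expected counts were rounded to whole numbers and summed to 17794423 in the empty vector library, 18439311 in the EVI1-WT library and 20772348 in the EVI1+18 library. The 10 most abundant genes took 5.48%, 5.81% and 6.01% of them. CPM values, counts relative to the library total, were scaled with TMM factors from edgeR 4.0.16 under R 4.3.3, which were 1.01, 0.990 and 0.996. Genes with a mean of at least 50 counts over the 3 libraries, 10406 in all, are described. A gene counts as higher or lower when its ratio of scaled counts is at least 2-fold, a fixed rule of size. Each ratio has an exact 95% interval (Clopper-Pearson, conditional on the sum of the 2 counts), computed with scipy 1.17.1 under Python 3.11.15. Reads without molecular identifiers are not independent molecules, and the intervals and the floor of 3 counts cover counting error only, not differences between cultures. A count of 0 was replaced by the floor of 3 counts per library, and the ratio is then given as a bound.

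31 gene lists were fixed before the data were examined, as were the 3 comparisons and the alternatives, except where stated. They cover erythroid, globin, heme synthesis, megakaryocyte, granulocyte and monocyte, mast cell, stem cell and lymphoid genes, reported EVI1 targets and partners, signalling and stress responses, the cell cycle, metabolism, ribosomal proteins, MHC class I, adhesion, and markers of packaging or stromal cells and of RNA quality. For each list with at least 5 members at a mean of 10 counts or more, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stands apart when its median lies outside the middle 95% of those lists, which describes these libraries and is not a test of the constructs. In each comparison 28 lists could be placed, of which 1.4 would stand apart if their members were random genes. Members of a list can vary together, so more may stand apart between single cultures without an effect of the construct. Counts of list members past 2-fold cover members with a mean of at least 50 counts, and those above or below a ratio of 1 cover all measured members. Lists share members, so they are not independent.

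The genes named are MECOM, the gene that codes for EVI1, and in each comparison the 8 higher and 8 lower genes whose interval bound nearest to 1 was most extreme. Symbols of uncharacterised loci, small RNAs and antisense transcripts were left out. Of each list up to 4 members past 2-fold were named, or up to 2 where the list did not stand apart, by size of the log2 ratio, and up to 2 of the most abundant members where none passed. HBE1, HBD, CA1, SLC4A1, ALAS2, FECH, GATA2, RUNX1, IER2, SQLE, FDFT1, BNIP3, VEGFA, GAPDH and FN1 are also named in places outside that rule, as list members chosen after their values were seen. Some genes and 1 list that fall under the rule are not reported here.

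Both EVI1 libraries were compared with the same empty vector library. The overlap of the calls was therefore set beside the product of the list sizes over all described genes, and beside 100 simulations of unchanged libraries against that control, with counting noise alone and with library noise (log2 SD of 0.134) taken from the spread between the EVI1 libraries. The empty vector reads were also split at random into 2 parts, one for each comparison. Alternatives were DESeq2 1.42.0 size factors, library totals, TPM with a pseudocount of 0.1, other count minimums, other fold rules, prior counts of 2 and 8, thinning to the smallest library, and other list summaries. Leaving out 636 genes that share reads was added after the data were seen. Ratios and lists were tested on simulated data of 10406 genes, 200 of them changed, with counting noise only. There the intervals covered the true ratio in 95.4%, 95.3% and 95.5% of genes for EVI1-WT against empty vector, EVI1+18 against empty vector and EVI1+18 against EVI1-WT. In each of these, 50 of 50 genes with a true fold of 2.5 and 0 of 50 with a true fold of 1.5 passed the 2-fold rule, as did 0 unchanged genes.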

Results

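EVI1 is a zinc finger transcription factor whose gene, MECOM, is rearranged in some myeloid leukaemias. Gene expression was measured in K562 cells carrying an empty retroviral vector, EVI1-WT or EVI1+18, a form that the title of the series ties to aberrant splicing. The labels do not say what the number in its name counts. There was 1 library per construct, with 17794423 counts for the empty vector, 18439311 for EVI1-WT and 20772348 for EVI1+18. At this depth 14454, 14116 and 14547 genes had at least 1 count. Ratios below are of scaled counts, with the exact 95% counting interval after the ratio. No difference has a replicate check, and each ratio compares these libraries rather than the constructs.

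MECOM was higher in both libraries made from EVI1 vectors. It had 793 counts (43.9 CPM) with empty vector, 1039 (56.9 CPM) with EVI1-WT and 2012 (97.3 CPM) with EVI1+18. The ratio to empty vector was 1.30 for EVI1-WT (1.18 to 1.42) and 2.21 for EVI1+18 (2.04 to 2.41). EVI1+18 exceeded EVI1-WT 1.71-fold (1.59 to 1.84). With EVI1-WT the log2 ratio of 0.37 was below the 95th percentile of all 10406 described genes, 0.42. That rise therefore lies within the scatter of genes between these libraries. With EVI1+18 the log2 ratio of 1.15 was above that percentile, 0.49. The gene tables do not separate the cell's own transcript from that of the vector, and whether all reads of the vector's EVI1 sequence are counted under MECOM could not be seen from them.

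The first comparison, EVI1-WT with empty vector, asks which transcripts differ in K562 cells given the vector of the unaltered form. Only RNA was measured here. The MECOM rise in that library lay within the scatter of genes, so MECOM counts alone do not establish expression from the vector there. Cyclin D1 and the early response factor EGR1 were far lower with EVI1-WT, the cholesterol synthesis genes and histone genes were lower as groups, and erythroid, heme synthesis and hypoxia genes were higher as groups. Of 10406 genes, 73 were at least 2-fold higher and 177 at least 2-fold lower, together 2.40%, while 93.7% differed by less than 1.5-fold. CCND1, which codes for cyclin D1, was 17.9-fold lower (10.6 to 32.4; 265 counts with empty vector and 15 with EVI1-WT). EGR1 was 11.6-fold lower (10.1 to 13.4; 2441 and 213 counts). ZNF618, a zinc finger gene, was 21.2-fold lower (13.3 to 36.2), and DAB2, an adaptor of endocytosis, 10.7-fold lower (6.43 to 19.2). MRAS, a small GTPase of the RAS family, had 96 and 2 counts, a ratio 48.6-fold lower with a wide interval (13.1 to 407).

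DACH1, a transcriptional regulator, was 16.2-fold higher with EVI1-WT (10.9 to 25; 26 and 425 counts). PPFIA4, a liprin gene, was 9.80-fold higher (5.26 to 20.2). OSGIN1, a gene induced by oxidative stress, was 5.40-fold higher (4.27 to 6.88), and SLC16A9, of the monocarboxylate transporter family, 5.05-fold higher (3.97 to 6.51). H19, an imprinted long non-coding RNA, was 3.59-fold higher (3.31 to 3.90; 743 and 2696 counts). The rule also picked 6 genes that share reads with a copy or a read-through partner and are uncertain: SMN2, TICAM2 and FAM133DP among the higher, and MAGEA9B, TVP23C-CDRT4 and BLOC1S5-TXNDC5 among the lower. With partners added, chosen after the values were seen, the ratio was 1.13 for SMN1 and SMN2, 0.971 for the TICAM2 set, 1.03 for FAM133B and FAM133DP and 1.15 for TXNDC5 with BLOC1S5-TXNDC5. MAGEA9 with MAGEA9B stayed 2.58-fold lower and TVP23C with TVP23C-CDRT4 2.79-fold lower.

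Erythroid genes were mostly higher with EVI1-WT, with 24 of 31 measured members above a ratio of 1 and a median log2 ratio of 0.25, though 2 of the 29 with a mean of at least 50 counts passed 2-fold. GYPB, a glycophorin of the red cell membrane, was 2.52-fold higher (2.24 to 2.84) and RHCE, a blood group gene, 2.01-fold higher (1.67 to 2.44). Both resemble a neighbouring gene and are uncertain, and the sums were at 2.13 with GYPE (2.01 to 2.27) and at 1.98 with RHD (1.74 to 2.25). The embryonic globin HBE1 was 1.94-fold higher (1.91 to 1.96; 32869 and 64351 counts). Of the same 29 members, 6 were at least 1.5-fold higher and 3 at least 1.5-fold lower, the latter the globin HBD, 1.77-fold (1.38 to 2.29), CA1, a carbonic anhydrase, 1.70-fold (1.24 to 2.34) and SLC4A1, an anion exchanger, 1.67-fold (1.26 to 2.21). Among the heme synthesis enzymes, 8 of 9 were above a ratio of 1 and the median was 0.43. ALAS2, the erythroid enzyme of the first step, was 1.60-fold higher (1.45 to 1.76) and FECH, which inserts iron, 1.47-fold higher (1.39 to 1.55), while UROD was at a ratio of 0.897 (0.868 to 0.928). The globin list had a median of 0.20. HBG2 was at 1.41 and HBG1 at 1.20, and since their reads can be exchanged their sum, at 1.33, is the firmer value. All 3 lists stood apart from random lists, but the globin list did so neither when its mean was used nor when members down to 1 count entered.

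Genes of cholesterol synthesis and its control were lower as a group. All 24 measured members were lower with EVI1-WT, 14 by at least 1.5-fold and 6 by at least 2-fold, with a median log2 ratio of -0.68 that was below all random lists. INSIG1, which holds back sterol-regulated transcription, was 2.88-fold lower (2.74 to 3.03; 5905 and 2075 counts). The mevalonate kinase gene MVK was 2.23-fold lower (1.95 to 2.57), SQLE 1.82-fold lower (1.73 to 1.90) and FDFT1 1.83-fold lower (1.76 to 1.92).

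Immediate-early genes of the AP-1 and MAPK pathway were lower in 18 of 26 cases, with a median of -0.29. EGR1 led them, FOS was 9.44-fold lower on 56 and 6 counts (4.08 to 26.8), and IER2 was 1.81-fold lower (1.69 to 1.94). Reported EVI1 targets had the same median, -0.29, with 2 lower and 1 higher past 2-fold. FOS is one of them, CDKN1A, an inhibitor of cyclin-dependent kinases, was 4.77-fold lower (2.96 to 8.04), and ALDH1A1, an aldehyde dehydrogenase of stem cells, was 3.14-fold higher (2.85 to 3.47; 539 and 1712 counts). GATA2, often described as raised by EVI1, was 1.44-fold lower (1.37 to 1.51), and RUNX1 was 1.61-fold higher (1.49 to 1.74). Restricted to targets with a mean of at least 50 counts, the list's median was -0.10 and no longer stood apart.

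Several other lists were also lower. Replication-dependent histone genes were lower in 15 of 16 cases with a median of -0.86, and HIST2H4A, uncertain because its reads were split evenly with its copy HIST2H4B, was 3.03-fold lower, with the sum at a ratio of 0.330 (0.259 to 0.417), HIST1H2BC 2.33-fold (1.78 to 3.06) and HIST1H1C 2.13-fold (2.05 to 2.22). The histone list was fixed as a sign of RNA quality, since most of these transcripts lack a poly(A) tail. Megakaryocyte and platelet genes had a median of -0.35 over 14 members, with the collagen receptor GP6 2.75-fold lower (2.19 to 3.50). NF-kB genes were below a ratio of 1 in 12 of 12 cases with a median of -0.32, and 0 of the 8 with a mean of at least 50 counts passed 2-fold. MHC class I genes were below it in 7 of 8 cases with a median of -0.29, although B2M was at 1.04 (1.0 to 1.07) and TAP2 at 1.39-fold lower (1.28 to 1.5). TGF-beta response genes had a median of -0.12, with ID3 2.15-fold lower (1.46 to 3.19) beside CDKN1A, and the MYC and nucleolar list one of -0.06, with NPM1 at 0.986 (0.974 to 0.998). The NF-kB, MHC class I, TGF-beta and MYC lists no longer stood apart when the mean of the list replaced its median.

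Hypoxia and glycolysis genes were above a ratio of 1 in 22 of 26 cases with a median of 0.29. ANKRD37, a target of the hypoxia response, was 3.76-fold higher on 15 and 57 counts (2.10 to 7.14) and was the 1 member past 2-fold among the 25 with a mean of at least 50 counts. BNIP3 was 1.76-fold higher (1.63 to 1.91), VEGFA 1.42-fold (1.32 to 1.53) and GAPDH 1.19-fold (1.18 to 1.20). Among genes from lists that did not stand apart, FCGR2A, an Fc receptor, was 2.03-fold lower (1.86 to 2.23), and the apoptosis regulator BOK was 3.74-fold lower (2.40 to 6.0). The inducible chaperone HSPA6 was 3.54-fold lower (2.34 to 5.51) and, since it shares reads with HSPA7, is uncertain, with the sum 2.98-fold lower, the integrin gene ITGB5 2.02-fold lower (1.76 to 2.32), the interferon-responsive CMPK2 2.26-fold higher (1.89 to 2.72) and INPP5D, a lipid phosphatase of blood cells, 3.84-fold higher (2.5 to 6.11).

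**Figure D1:**
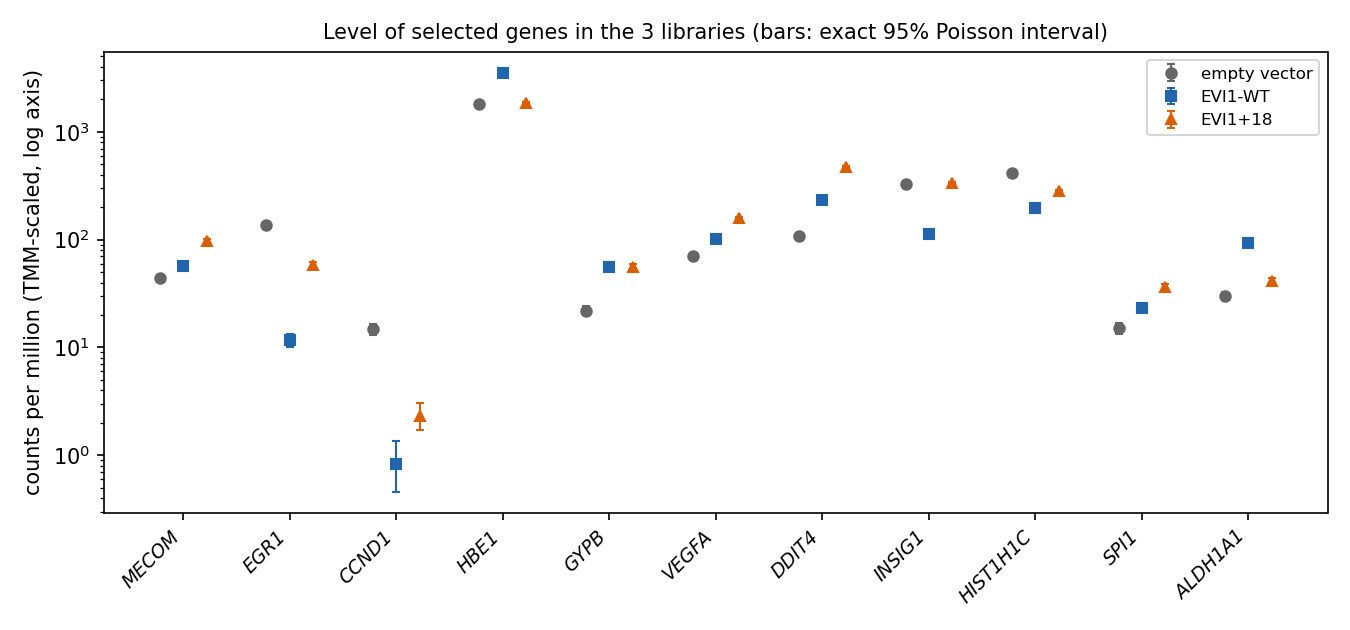
Scaled counts (CPM, log axis) of 11 genes in the empty vector (circles), EVI1-WT (squares) and EVI1+18 (triangles) libraries, with exact 95% Poisson intervals. EGR1 and INSIG1 are lowest with EVI1-WT, whereas MECOM, VEGFA, DDIT4 and SPI1 are highest with EVI1+18.

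The second comparison sets EVI1+18 against the same empty vector library. Several hypoxia and glycolysis genes were among those higher, as were DDIT4 and the myeloid factor SPI1, while CCND1 and ZNF618 were again among the lowest. At least 2-fold higher were 105 genes and at least 2-fold lower 87, together 1.85% of 10406, and 94.5% differed by less than 1.5-fold. DDIT4, a stress-induced inhibitor of MTOR signalling, was 4.36-fold higher (4.15 to 4.58; 1954 and 9758 counts). PPFIA4 was 13.2-fold higher (7.17 to 26.9), INPP5D 7.59-fold (5.09 to 11.8), the WNT receptor gene FZD3 7.07-fold (4.38 to 12.1), FHDC1, a formin-type gene, 5.26-fold (3.72 to 7.62) and H19 4.14-fold (3.83 to 4.49). ZNF618 was 27.1-fold lower (16.5 to 47.9), ENAH, a regulator of actin, 12.6-fold (6.80 to 25.9; 121 and 11 counts), NAV1 6.92-fold (5.40 to 8.98), CCND1 6.33-fold (4.64 to 8.80), SAMD5 6.29-fold (4.41 to 9.19) and PM20D2 6.14-fold (4.08 to 9.55). The read-through gene COMMD3-BMI1, with 273 and 0 counts, shares reads with COMMD3 and BMI1, whose sum with it was at a ratio of 0.877. TICAM2 was higher and MAGEA9B lower by the rule as well, with sums at 0.869 and 0.554, so these genes are uncertain too.

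In the hypoxia and glycolysis list, 23 of 26 members were above a ratio of 1 with EVI1+18 and 6 of the 25 with a mean of at least 50 counts passed 2-fold, for a median of 0.48. ANKRD37 was 7.5-fold higher (4.38 to 13.8). PFKFB4, a regulator of glycolysis, was 2.72-fold higher (2.46 to 3.02), P4HA1, a collagen prolyl hydroxylase, 2.44-fold (2.25 to 2.64), ENO2 2.41-fold (1.99 to 2.93) and VEGFA 2.23-fold (2.09 to 2.38). GAPDH was 1.38-fold higher (1.37 to 1.39). Genes of the unfolded protein and amino acid stress list had a median of 0.19 with 22 of 26 above a ratio of 1, and CHAC1, which degrades glutathione, was 2.38-fold higher (1.86 to 3.06).

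The globin list was above a ratio of 1 in 8 of 8 cases, with a median of 0.42. HBG2 was at 1.47 (1.46 to 1.48) and HBG1 at 1.36 (1.35 to 1.37), and their sum at 1.43. HBE1 was at 1.02 (1.01 to 1.04). The erythroid list had a median of 0.19, with GYPB 2.53-fold higher (2.26 to 2.85) as its 1 member past 2-fold, and 1.84-fold with GYPE added. Heme synthesis enzymes had a median of 0.25, and ALAS2 was at 1.37 (1.24 to 1.5) and UROD at 0.981. Cytosolic ribosomal protein genes were above a ratio of 1 in 38 of 38 cases with a small median of 0.16, RPLP0 at 1.09 (1.08 to 1.10) and RPL4 at 1.05 (1.04 to 1.07). The interferon list stood apart at the 97.6th percentile, with a median of 0.27, 0 of the 9 members with a mean of at least 50 counts past 2-fold and BST2 at 1.15 (1.09 to 1.21). That call was lost under several alternatives, with TPM among them.

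Cholesterol synthesis genes were lower with EVI1+18 in 20 of 24 cases, with a median of -0.16 and none past 1.5-fold. INSIG1 was at 1.03 (0.992 to 1.06). Histone genes were lower in 13 of 16 cases with a median of -0.41, HIST1H1C 1.47-fold (1.42 to 1.52) and HIST1H2BK 1.29-fold (1.25 to 1.32), and with the mean of the list they no longer stood apart. The granulocyte and monocyte list lay just inside the range of random lists, at a median of 0.25. It stood apart with TPM (0.15), with members from a mean of 50 (0.25) or 1 (0.40) and with the mean of the list (0.37). Within it SPI1, which codes for the factor PU.1, was 2.40-fold higher (2.08 to 2.77; 271 and 745 counts) and CYBB, a subunit of the phagocyte oxidase, 2.04-fold higher (1.51 to 2.78). EGR1 was 2.31-fold lower (2.16 to 2.48) and ATF3 2.02-fold higher (1.67 to 2.45), within an immediate-early list at a median of 0.05. CDKN1C, a cell cycle inhibitor, was 2.34-fold higher (1.97 to 2.79), GP6 2.87-fold lower (2.29 to 3.61) and GATA2 1.36-fold lower (1.30 to 1.42).

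The third comparison, EVI1+18 with EVI1-WT, asks where the libraries of the spliced form and the unaltered one differ. MECOM was 1.71-fold higher with EVI1+18, so form and amount of transcript cannot be told apart here. This comparison uses the same EVI1-WT library as the first comparison. A deviation of that library would appear in both, as lower with EVI1-WT there and as higher with EVI1+18 here. Most of the genes past 2-fold were higher with EVI1+18. They numbered 99, against 22 lower, together 1.16% of 10406 genes, and 95.6% differed by less than 1.5-fold. EGR1 was 5.01-fold higher with EVI1+18 than with EVI1-WT (4.33 to 5.82; 1209 and 213 counts) and FOS 13.2-fold (5.85 to 37.0; 90 and 6 counts). SLIT2, a secreted guidance factor, was 8.69-fold higher (6.27 to 12.4), the phosphatase gene CTDSPL 5.59-fold (3.92 to 8.18) and MRAS, on 91 and 2 counts, 40.2-fold (10.8 to 337). DACH1 was 26.8-fold lower (16.7 to 45.6), ENAH 13.1-fold (7.07 to 26.9), the desmosomal gene PKP2 6.60-fold (4.40 to 10.2), the lipoprotein lipase gene LPL 4.04-fold (3.14 to 5.24), ARHGAP15 4.29-fold (2.35 to 8.37) and CRIM1 3.26-fold (2.39 to 4.50). BLOC1S5-TXNDC5, TVP23C-CDRT4, COMMD3-BMI1 and SMN2 were picked as well and share reads with their partners. The sums were at 0.934, 2.04, 0.869 and 0.865.

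Cholesterol synthesis genes were higher with EVI1+18 than with EVI1-WT in 22 of 24 cases, at a median of 0.51. INSIG1 was 2.96-fold higher (2.82 to 3.11) and SQLE 1.45-fold (1.38 to 1.52). Hypoxia and glycolysis genes were higher in 24 of 26 cases at a median of 0.25, 0 of 25 past 2-fold, with VEGFA at 1.57 (1.48 to 1.66), ENO1 at 1.19 (1.18 to 1.20) and GAPDH at 1.16 (1.15 to 1.17). Immediate-early genes had a median of 0.22, led by FOS and EGR1, and TGF-beta response genes one of 0.20, with CDKN1A 2.65-fold higher (1.59 to 4.57) and BHLHE40 2.20-fold (2.04 to 2.37). Granulocyte and monocyte genes were higher in 10 of 11 cases, with a median of 0.46 and FCGR2A at 1.87 (1.71 to 2.04), while CD68 was 1.33-fold lower (1.21 to 1.47). Histone genes were higher in 14 of 16 cases at a median of 0.47, with HIST1H1C at 1.45 (1.39 to 1.51), and MHC class I genes in 8 of 8 at 0.31, with TAP2 at 1.11 (1.03 to 1.20).

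Globin genes had a median of 0.25 between the EVI1 libraries, with HBG1 at 1.14 (1.13 to 1.15), HBG2 at 1.04 (1.04 to 1.05) and their sum, the firmer value, at 1.07 (1.07 to 1.08), although HBE1 was 1.89-fold lower with EVI1+18 (1.87 to 1.92). The erythroid list, at -0.04, and the heme synthesis list, at -0.07, did not stand apart. Small medians above those of random lists were found for the stress list at 0.12, with HSPA5 at 1.08 (1.05 to 1.11), and ribosomal protein genes at 0.09. The NF-kB list was at 0.25, with RELA at 1.14 (1.06 to 1.23), and the adhesion list at 0.18, with VIM at 1.30 (1.26 to 1.35). Heat shock genes were lower in 14 of 17 cases at a median of -0.15, although HSPA6 was 3.47-fold higher (2.31 to 5.37) and its sum with HSPA7 2.96-fold. Markers of HEK293-type packaging cells were higher in 5 of 6 cases at a median of 0.65. DLK1, also present with empty vector at 433 counts, was 3.04-fold higher (2.70 to 3.43). That list did not stand apart against empty vector, at -0.30 with EVI1-WT and 0.18 with EVI1+18, but the mean of the list did for EVI1+18, at 0.57. The globin, histone, MHC class I, NF-kB, adhesion and heat shock lists no longer stood apart with the mean of the list.

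Several list medians did not stand apart in any comparison under the main settings. For EVI1-WT against empty vector, EVI1+18 against empty vector and EVI1+18 against EVI1-WT, the cell cycle and DNA replication list had medians of 0.06, -0.003 and -0.08, with MCM7 at 0.903, 1.01 and 1.12 and TOP2A at 0.995, 0.857 and 0.861. The cyclin and p53 target list had 0.01, 0.04 and 0.09, the apoptosis list -0.04, -0.01 and 0.06, and nuclear oxidative phosphorylation genes 0.06, 0.04 and -0.02. EVI1 partners and chromatin modifiers had -0.04, 0.04 and 0.02, with DNMT1 at 0.980, 0.986 and 1.01. Stem cell and leukaemia genes, transcription factors and others such as KIT and ALDH1A1, had -0.07, -0.03 and 0.02. With EVI1-WT the stem cell list stood apart with members from a mean of 50 (-0.12) or 1 (-0.21), and between the EVI1 libraries the cyclin list did with its mean (0.27). Some of these small medians change sign with TPM, such as that of the cell cycle list with EVI1-WT, and no direction is read from them.

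Both EVI1 libraries shared many of the genes that differed from empty vector. Of the 73 genes higher with EVI1-WT and the 105 higher with EVI1+18, 50 were shared, among them PPFIA4, H19 and ANKRD37. Of the 177 and 87 lower genes, 62 were shared, among them CCND1, ZNF618 and EGR1. Independent lists of these sizes would share 0.737 and 1.48 genes. Unchanged libraries simulated against the same control shared 0.13 and 0.01 genes on average with library noise, and at most 2 and 1. The simulated noise was normal with the same SD for every gene, so it seldom reached 2-fold. Yet 121 genes passed 2-fold between the EVI1 libraries themselves. Genes that deviate that far in the control alone are not simulated, so the simulated overlap is too low a benchmark for them. With the empty vector reads split once at random between the comparisons, 41 and 62 were shared. Splitting reads removes shared counting error but not a deviation of the 1 control culture, so part of the excess may come from the shared control. Across genes, which are not independent replicates, the log2 ratios correlated at r = 0.61, and at 0.529 with the empty vector reads split. In the simulation with library noise r was 0.505. The covariance of the log2 ratios was 0.0781, and 0.0717 with the reads split, against 0.0245 in that simulation. Opposite directions past 2-fold were seen for 3 genes, with SLIT2 and SMN2 among them.

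**Figure D2:**
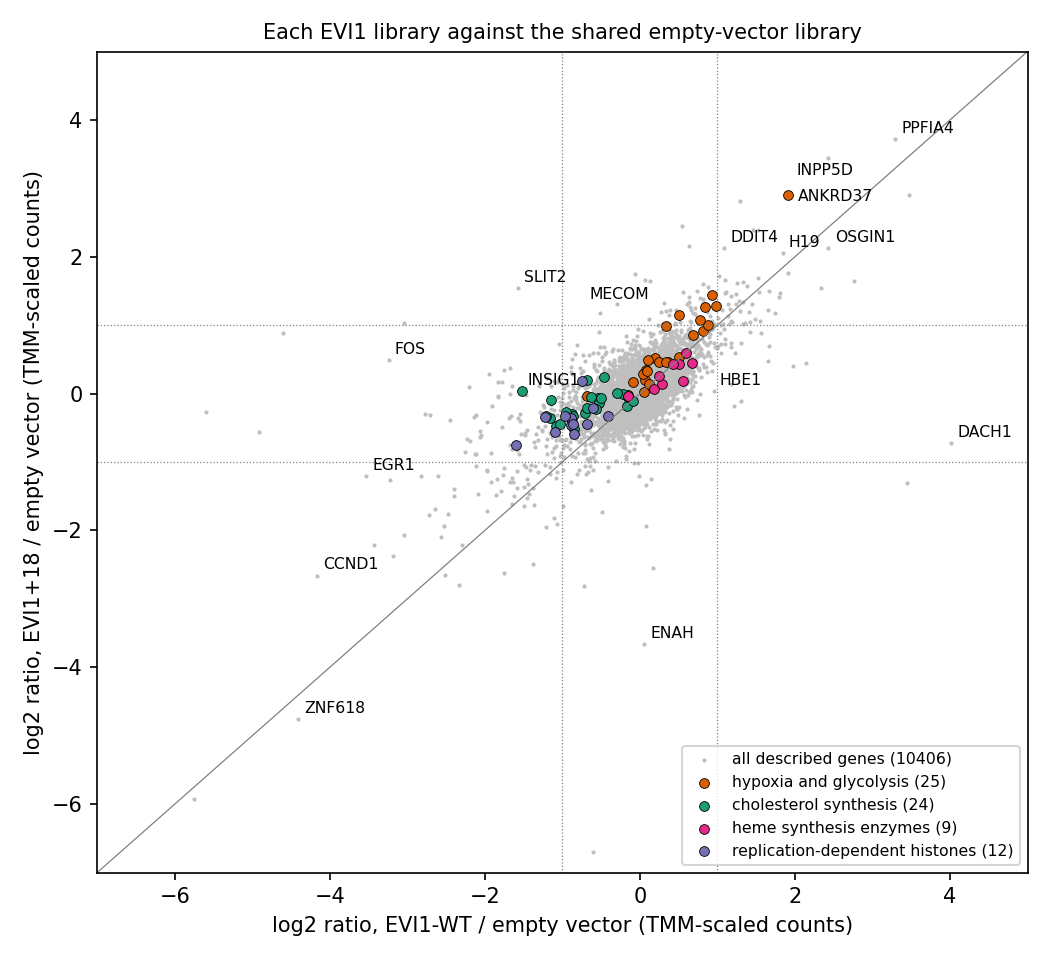
Log2 ratio to empty vector of 10406 genes with EVI1-WT (x axis) and EVI1+18 (y axis), with dotted lines at 2-fold and 4 gene lists in colour. Most hypoxia and glycolysis genes lie at upper right, while cholesterol synthesis genes spread to the left (median -0.68) and less downward (median -0.16).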

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

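No test of these differences was planned or run, since each construct has 1 library. For 3 genes the EVI1 libraries lay on opposite sides of empty vector by at least 2-fold each, a difference that was not tested, and 2 of them are given here. SLIT2, with 118, 40 and 394 counts for empty vector, EVI1-WT and EVI1+18, had log2 ratios to empty vector of -1.58 and 1.54. SMN2, with 28, 310 and 13 counts, had 3.45 and -1.30, but it shares reads with SMN1, and the sum of both genes differed from empty vector by ratios of 1.13 and 0.976.

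The length column, which the comparisons do not use, held a lower weighted transcript length for MECOM in both EVI1 libraries. It was 5042.46 bases with empty vector, 4936.02 with EVI1-WT (97.9%) and 4876.12 with EVI1+18 (96.7%). Among the 10406 described genes, 308 (2.96%) had a larger relative drop with EVI1-WT and 201 (1.93%) with EVI1+18. The labels do not give the length of the vector's transcript.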

How the results depend on the processing

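No paired analysis was possible because each construct has 1 library, and for the same reason no replicate could be left out. No direction reversed for any list that stood apart, or for any named gene past 2-fold under DESeq2 size factors, library totals and TPM. Other called genes were not checked for reversal. These scalings change most ratios by far less than 2-fold, so this was a weak check of the ratios. Leaving out genes that share reads was chosen after the data were seen. The 2-fold counts stayed within 1.5 times under DESeq2 size factors, library totals, TPM, both prior counts, thinning and without genes that share reads. TPM moved the median of all described genes by -0.10 (log2) for EVI1+18 against empty vector, and the share of higher calls there from 54.7% to 44.9%. Counts at other limits are higher then lower, for EVI1-WT against empty vector, EVI1+18 against empty vector and EVI1+18 against EVI1-WT. With a mean of at least 10 counts they were 210 and 481, 295 and 282, and 359 and 96. At a mean of 200 they were 26 and 48, 40 and 19, and 24 and 3, and with no filter 393 and 942, 596 and 679, and 717 and 314. The 1.5-fold rule gave 247 and 411, 343 and 232, and 372 and 88, and the 3-fold rule 21 and 77, 24 and 30, and 31 and 8. With the whole interval beyond 2-fold they were 34 and 103, 45 and 46, and 45 and 12. Genes shared by both EVI1 libraries, higher and lower, numbered 158 and 146 at 1.5-fold, 9 and 17 at 3-fold, 130 and 179 at a mean of 10 and 17 and 13 at a mean of 200. Why the counts shift between limits was not tested. For EVI1+18 against empty vector the balance shifted too, from 54.7% of calls higher in the main setting. The share was 67.8% at a mean of 200, 46.7% with no filter and 44.4% at 3-fold. Both MECOM ratios kept their value within counting error under DESeq2 size factors, library totals and TPM. Of 573 alternative ratios of named genes, 484 stayed inside the counting interval and 89 did not.

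Of 498 alternative list values, 463 left the list on its side of the random range, 21 ended a call and 14 made one; the causes were not tested. Medians or means after the change are given. For EVI1-WT against empty vector, calls ended for reported EVI1 targets at members with a mean of 50 (-0.10), for globins at a mean of 1 (0.13) and, with the mean of the list, for globins (0.19), TGF-beta (-0.16), MYC (-0.039), NF-kB (-0.54) and MHC class I (-0.33). For EVI1+18 against empty vector, the interferon call ended with TPM (0.14), at a mean of 50 (0.25), at 1 (0.23) and with the mean (0.25), and the histone call with the mean (-0.31). Between the EVI1 libraries, adhesion ended with TPM (0.12), at a mean of 1 (0.17) and with the mean (0.20), NF-kB at a mean of 50 (0.17) and with the mean (0.37), and globins (0.17), histones (0.42), heat shock (-0.020) and MHC class I (0.36) with the mean, which left 0 lists lower. Calls appeared for EVI1-WT against empty vector in the stem cell list at a mean of 50 (-0.12) and 1 (-0.21), fibroblast markers at 1 (-1.31) and with the mean (-1.15), and the stress list with the mean (0.11). For EVI1+18 against empty vector they appeared for granulocyte genes with TPM (0.15), at 50 (0.25), at 1 (0.40) and with the mean (0.37), fibroblast markers at 1 (-0.83), megakaryocyte genes (-0.62) and packaging cell markers (0.57) with the mean. Between the EVI1 libraries they appeared with the mean for reported targets (0.44) and cyclins (0.27). Counting error weighs most on genes near the count minimum, though with counting noise alone 0 unchanged genes passed 2-fold in the simulated data. More depth would not replace replicate cultures.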

Other observations

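Lineage genes outside the erythroid program also differed from empty vector, in 2 lists with too few measured members for a median and in 1 list whose median did not stand apart. PTPRC, which codes for the leukocyte antigen CD45, had 568 counts with empty vector, 216 with EVI1-WT and 300 with EVI1+18, and was 2.66-fold lower (2.27 to 3.13) and 2.17-fold lower (1.88 to 2.5). CD3D, of the T cell receptor complex, had 179, 59 and 73 counts and was 3.07-fold (2.27 to 4.19) and 2.81-fold lower (2.13 to 3.74). They were the 2 measured members of the lymphoid list. Of the 3 measured mast cell, basophil and eosinophil genes, PRG2, an eosinophil granule protein, had 36, 38 and 131 counts and was at 1.04 with EVI1-WT (0.644 to 1.69) and 3.17-fold higher with EVI1+18 (2.18 to 4.73), both against empty vector. KIT was at 1.07 (0.839 to 1.37) and 1.56 (1.25 to 1.95), while GATA2, the most abundant of the 3, was 1.44-fold (1.37 to 1.51) and 1.36-fold lower (1.30 to 1.42). SPARC, a matrix protein among 6 measured stromal markers, had 97, 25 and 34 counts and was 3.93-fold lower (2.51 to 6.36) and 3.27-fold lower (2.19 to 4.99). That list's median, -0.14 with EVI1-WT, 0.19 with EVI1+18 and 0.47 between them, did not stand apart, but with members down to a mean of 1 count it did, at -1.31 and at -0.83, where the sign with EVI1+18 turned, and with its mean for EVI1-WT at -1.15. FN1, its most abundant member, was 1.38-fold higher with EVI1-WT (1.26 to 1.51) and at 1.05 with EVI1+18 (0.955 to 1.15). Of the mitochondrially encoded genes 0 were measured, so that list gave no value.

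The tests in the next paragraphs were chosen after the results were seen, except those of GC content and length, whose corrected values had not been seen. GC content was at hand for 94.7% of the genes lists draw on and for 100% of the members tested. Culture state was not measurable with 1 library per construct and stays open for all 3 patterns.

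Cholesterol synthesis genes were lower with EVI1-WT than with empty vector. Removing trends on GC content and transcript length left the median at -0.7466, from -0.68, which argues against those biases as the cause. If the amount of EVI1 transcript counted under MECOM alone set these genes, with both forms acting alike, they would be at least as low with EVI1+18, which held more MECOM counts. The median of EVI1+18 against EVI1-WT was 0.5078, above random lists, so in these libraries the genes did not follow the order of MECOM counts. This value reuses the EVI1-WT library that defines the pattern, and a deviation of that culture would give it too. It therefore cannot decide whether the amount had a part. MECOM counts may miss part of the vector's transcript, so the full amount stays open. An effect of the EVI1 form was not tested and stays open, and a difference in density, medium or lipid supply of 1 culture cannot be told apart from it, since there is 1 library per construct.

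Hypoxia and glycolysis genes were higher with both EVI1 forms. With GC and length trends removed the medians were 0.2555 with EVI1-WT and 0.4859 with EVI1+18, close to those before. An unusual empty vector culture stays open, since there is 1 empty vector library. An effect of EVI1 was not tested and stays open, and culture density cannot be told apart from it, with 1 library per construct.

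Histone genes were lower with both EVI1 forms. Their medians after removal of GC and length trends were -0.8574 and -0.513, which argues against these trends as the cause. Histone transcripts are short (median 540 bases against 2894). The trends were removed in bins, so a length effect within a bin of short transcripts stays open. Fewer cells in S phase would lower DNA replication genes as well. The cell cycle list's median with EVI1-WT was 0.05633, with a member spread of 0.1419, so that list did not fall as a whole. It mixes genes of DNA replication with genes of mitosis, so its median cannot decide whether fewer cells were in S phase. Less carry-over of RNA without a poly(A) tail, if the kit selected for tails, may explain the pattern and cannot be told apart from an effect of EVI1, since 0 of 436 small non-coding RNA genes listed had enough counts to compare. The same holds for culture state, with 1 library per construct.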
